A study of Mus musculus with 6 samples.

How the data were processed

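RNA of quiescent and activated neural stem cells, sorted from the adult mouse ventricular-subventricular zone, was measured on 6 one-colour arrays, 3 per group. Per the labels' protocols, total RNA was purified with miRNeasy columns, amplified with the NuGEN Pico system and labelled with biotin. Groups and replicate numbers were taken from the sample labels, which call the arrays biological replicates. The deposited values are log2 signals, which the authors computed with MAS5, per the submitters' processing notes. The MAS5 version, detection calls and scanner settings are not given in the sources used here. From the values, the linear 2% trimmed mean was close to 500.0 on every array, and the lowest log2 value was 0. Scaling to a common trimmed mean removes any difference in total RNA per cell, and MAS5 values near background are noisy, which can inflate fitted differences of dim genes.

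The design had provided for adding 16 to linear signals. Because the values were already on a log2 scale, they were used as deposited with no pseudocount. The 64 control probe sets were left out of the tests. Of the remaining probe sets, 34945 were paired with 1 gene, 932 with several and 9160 with none in the platform annotation, and only the first kind was used for genes. Symbols were updated by Entrez identifier through a RefSeq gene table of assembly GRCm38.p6, used for names alone, in which 99.4% of the identifiers were found. The sources name no genome build, so no coordinates are given. Of several probe sets of a gene the brightest was kept, and the 18193 genes were filtered to the 11575 whose mean over the 6 arrays reached the 40th percentile of all probe sets, a log2 signal of 6.02.

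Groups were compared with lmFit and eBayes with a mean-variance trend in limma 3.58.1 under R 4.3.3, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. SE values of single genes come from this fit. Those of list medians reflect the spread over the genes of the list, not over arrays. Gene lists were fixed before the data were examined, from textbook knowledge and published themes of ventricular-subventricular zone stem cell biology. Those themes may rest on earlier comparisons of the same cells, so list shifts may not be independent of published work. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 31 lists. The 34 lists covered stem cell, progenitor, neuronal, glial, vascular, immune, blood and sex-linked genes, the cell cycle, DNA repair, chromatin, protein and RNA production, metabolism, lysosome, adhesion, receptors, channels, niche signalling, immediate early and interferon genes. Many list genes were not matched here to a probe set of 1 gene, only 43 of 76 ribosomal protein genes being matched. The dim filter removed others. It left 11 of 30 matched ependymal, 7 of 15 pericyte and 8 of 21 mature neuron genes. Technical measures were compared by two-sided exact permutation tests. Figures were drawn with matplotlib 3.10.9.

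Genes were named by a rule set before the data were examined: the 4 sort genes, the 10 largest called differences in each direction among genes whose arrays did not overlap and whose brighter group reached the median, and from each list up to 3 called genes of the main direction and 1 of the other. Additional oligodendrocyte, immediate early and heat shock genes, Xist and genes with opposed probe sets were named after their values were seen. Background was the 95th percentile of the 27 control probe sets for bacterial transcripts not expected in the sample. When an array of the lower group was at or below it, the fold is a lower bound, taken as the brighter group's mean against the mean of the larger of background and signal on each array of the lower group. This limit depends on the 27 probe sets.

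The calculation was tested on simulated data for 3 against 3 arrays over 11575 genes, 200 of them changed. It recovered 2.99% of genes changed by 1 on the log2 scale, 44.8% of those changed by 2 and 89.4% of those changed by 4. Of the 94 calls, 3.19% were false. In the real data 34.9% of genes were called. The adjusted p depends on the share of changed genes, so these percentages do not measure recovery in the real data. In a second simulation a list of 30 genes shifted by 1 was found and 0 of 30 unshifted lists were called. Genes were drawn independently there, so it does not test camera on lists whose genes vary together. Alternatives set beforehand were 2 pseudocounts, other scalings, filters, probe set rules and variance models, the replicate number as a block, each array left out in turn, and other list tests. Scaling to the hybridisation controls and raising values to background were chosen after seeing the data.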

Results

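Gene expression was compared between quiescent and activated neural stem cells of the adult mouse ventricular-subventricular zone, the neurogenic layer that lines the lateral ventricles of the brain. The cells were isolated by flow cytometry. Quiescent cells were positive for a GFP reporter driven by the GFAP promoter and for CD133, and negative for CD24. Activated cells met the same criteria and were also positive for the EGF receptor. Each population was measured on 3 one-colour arrays, which the labels describe as biological replicates, and the small number of arrays limits the precision of every value. Each array carried 45101 probe sets, and 11575 genes were bright enough to be tested. Values are log2 MAS5 signals and differences are activated minus quiescent on that scale, given ± SE from the limma fit with the Benjamini-Hochberg adjusted p (n = 3 arrays per group). Where at least 1 array of the lower group was at or below background, a lower bound on the fold is given. This bound compares group means and carries no SE, so single arrays above background can differ by less.

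The comparison asks which genes differ between dormant stem cells and stem cells that express the EGF receptor. The 4 genes behind the sort were examined first, because they check the labels. Egfr was 2.11 ± 0.24 higher in activated cells (adjusted p = 0.000153), rising from 10.8 ± 0.14 (SD) to 12.9 ± 0.15. Its protein separated the groups, so this difference is no finding. Of the 7 Egfr probe sets, 2 were not higher, with differences of -0.01 and -0.77. Gfap, which encodes an intermediate filament of astrocytes and adult neural stem cells, fell by 4.18 ± 0.58 (adjusted p = 0.000444), although both sorts required the GFAP reporter. Its further probe sets differed by -5.78 and -6.07. Activated array 1 read 2.53 and 1.16 for these, below its background of 4.67, which makes these differences imprecise. Prom1, which encodes CD133, fell by 1.22 ± 0.32 (adjusted p = 0.0133). The Prom1 call was lost without activated array 1 (adjusted p = 0.0594), without quiescent array 2 (adjusted p = 0.0551) and after scaling to the hybridisation controls (adjusted p = 0.309). Cd24a was 4.13 ± 0.50 higher in activated cells (adjusted p = 0.000223), although cells carrying CD24 protein were removed from both sorts, and its 3 probe sets differed by 3.45 to 4.13.

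**Figure D1:**
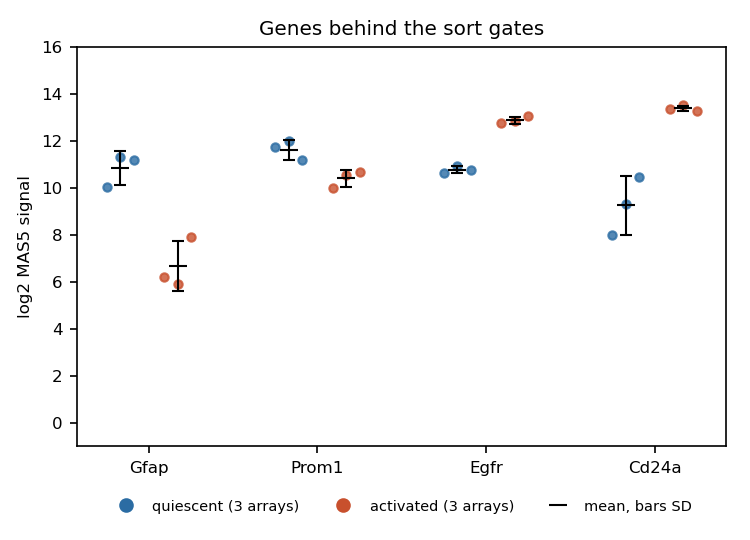
The log2 MAS5 signal (vertical axis) of the 4 genes behind the sort on each of the 3 quiescent and 3 activated arrays, with points for arrays, dashes for group means and bars for SD. Egfr and Cd24a were higher on every activated array, and Gfap and Prom1 on every quiescent array.

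A large part of the measured transcriptome differed. Of the 11575 genes tested, 4044 (34.9%) passed an adjusted p of 0.05 in limma, 2004 of them higher and 2040 lower in activated cells. At least 2-fold differences were found for 1849 genes that were higher and 1954 that were lower. The 3 arrays of one group lay entirely above those of the other for 3987 of the changed genes and for 50.7% of all tested genes, where chance gives 10%. Correlations between arrays were 0.835 to 0.862 among quiescent arrays, 0.895 to 0.903 among activated arrays and 0.743 to 0.805 between groups. Without activated array 2 the number of higher genes was 1315.

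Several technical measures moved with the groups. The hybridisation controls, which are added in equal amounts to each array, averaged 14.3 ± 0.53 (SD) on quiescent and 13.7 ± 0.05 on activated arrays. The array background was 5.67 ± 0.37 against 4.60 ± 0.07, and the difference between the 3′ and 5′ Gapdh control probe sets, a measure of RNA integrity, was 2.05 ± 0.52 against 1.37 ± 0.17. For each of these the two-sided exact permutation p was 0.1, the smallest that 3 arrays against 3 can give. The same measure from the actin control probe sets was -0.05 ± 0.16 against 0.07 ± 0.16 (exact permutation p = 0.4). Quiescent array 1 had the highest hybridisation controls, at 14.9, and the largest Gapdh difference, at 2.59. Scaling each array to its hybridisation controls, an alternative chosen after seeing the data, raised the median difference of all tested genes from 0.01 to 0.66 and gave 3059 higher and 943 lower genes. The share of changed genes that were higher was then 76.4%, against 49.6% with the deposited scaling. Differences of single genes are therefore relative to the deposited scaling.

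The genes with the largest increases in activated cells included several of cell division. Chaf1b, a subunit of the histone chaperone that assembles chromatin on replicated DNA, was at least 38.9-fold higher (adjusted p = 3.25e-05). Clspn, a replication checkpoint adaptor, was at least 31-fold higher (adjusted p = 0.000403), and Esco2, a cohesin acetyltransferase, at least 25.4-fold (adjusted p = 0.000448). Gtse1, Bub1 and Cenpn, which act in G2 and mitosis, were higher by at least 19.2-fold, 18.1-fold and 16.9-fold. The rest of the 10 were Lsm2, a splicing factor component (at least 63.9-fold, adjusted p = 0.00248), Tlcd3b (at least 31.4-fold), Mfap4 (at least 19.1-fold) and the proneural factor Neurod4 (at least 10.2-fold, adjusted p = 0.00545). All 3 quiescent arrays were at background for Tlcd3b, Chaf1b, Cenpn and Gtse1, and 2 of 3 for the other 6 genes. The quiescent array above background read 8.47 for Lsm2 (array 3) and 8.17 for Bub1 (array 2). Their activated means were 12.7 and 10.8.

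The 10 genes with the largest decreases were at least 42.9-fold lower in activated cells. Slc39a12, a zinc transporter, was at least 136-fold lower (adjusted p = 0.00026), and the transport ATPase Atp13a4 at least 109-fold lower (adjusted p = 0.000418). Il33, an alarmin cytokine, was at least 83.6-fold lower (adjusted p = 5.35e-05), the protocadherin Pcdh7 at least 69.3-fold (adjusted p = 3.25e-05), and the calcium-binding astrocyte protein S100b at least 42.9-fold (adjusted p = 0.000166). Lower bounds for the remaining genes were 57.1-fold for Eva1a, 55.3-fold for Aass, an enzyme of lysine breakdown, 54.0-fold for Shisa9, 51.9-fold for Aox1 and 44.0-fold for Slc22a4. All 3 activated arrays were at background for Il33, Pcdh7, Slc22a4, Aass and S100b.

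**Figure D2:**
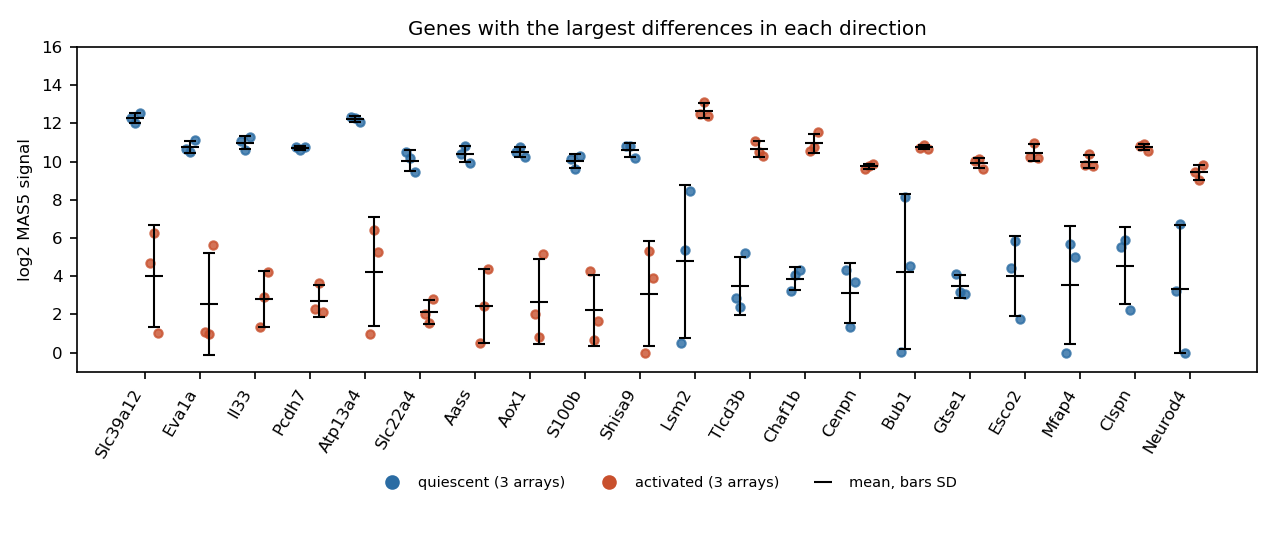
The log2 MAS5 signal (vertical axis) on each array of the 10 genes with the largest decreases and the 10 with the largest increases in activated cells, with points for arrays, dashes for group means and bars for SD. The arrays of the 2 groups do not overlap for any of these genes, and at least 1 array of the lower group read at or below background.

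Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01. Of 31 lists with enough tested members, 13 were shifted higher and 14 lower in activated cells, and 4 did not pass. With the correlation estimated from the data 0 lists were called by camera, 23 had an unadjusted p under 0.05, and the adjusted p of the called lists then lay between 0.0543 and 0.14. The 31 directional fry tests, which ask whether a list's genes move on balance one way, all passed. They included the 4 lists that camera did not call, such as Notch (fry adjusted p = 0.027) and cell cycle brakes (fry adjusted p = 0.0456). Fry therefore does not separate shifted from unshifted lists here.

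**Figure D3:**
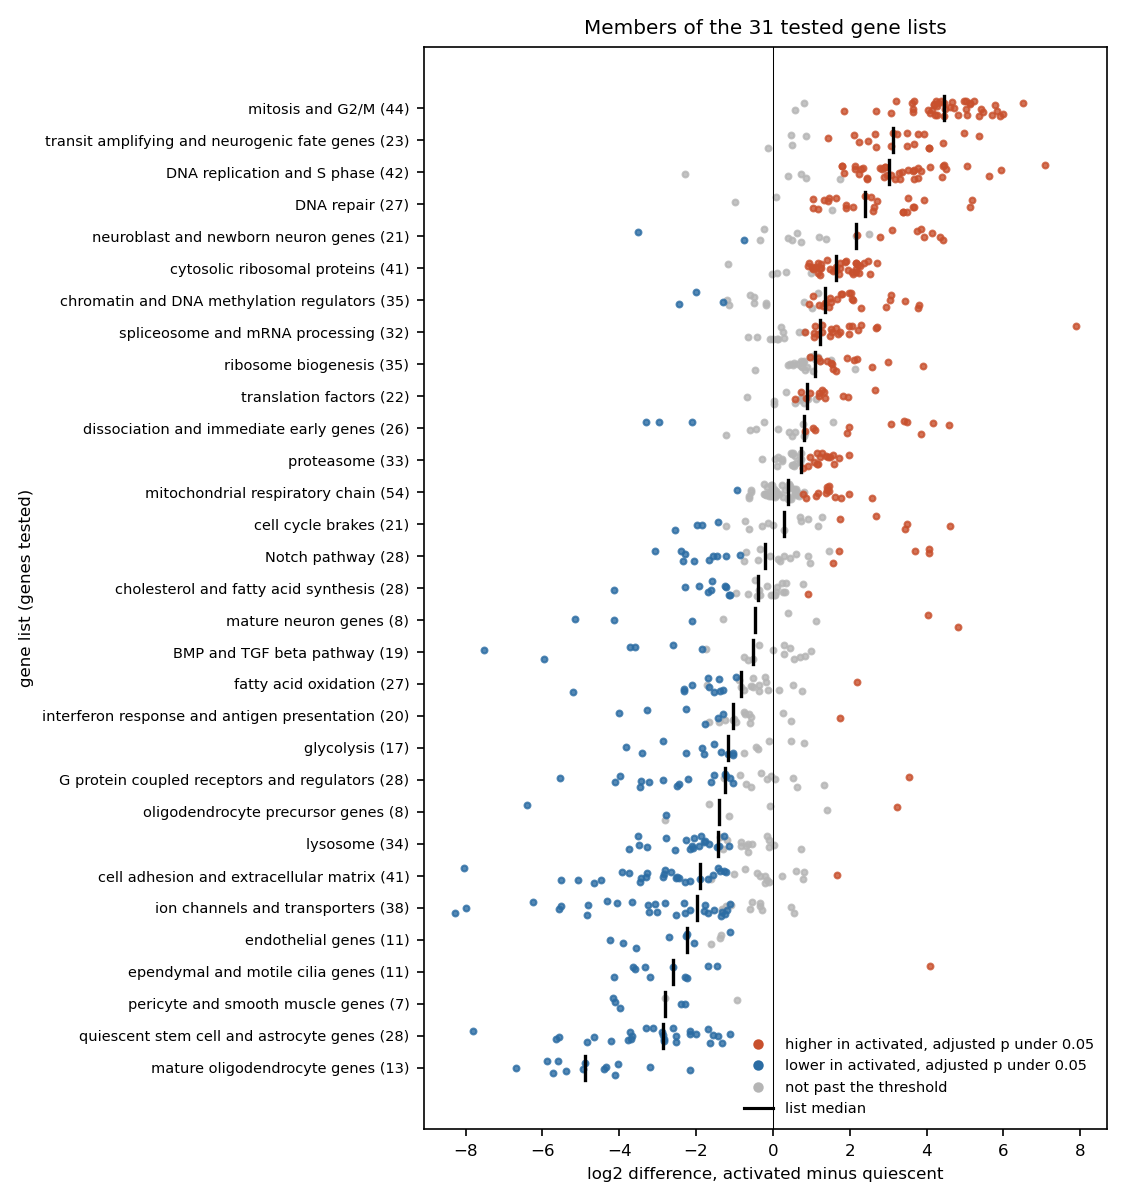
Log2 differences (horizontal axis, activated minus quiescent) of the tested members of each of the 31 gene lists (vertical axis, number of tested genes in parentheses), where a point is a gene, its colour shows the limma call and a black line is the list median. Medians ran from -4.89 for mature oligodendrocyte genes to 4.46 for mitosis and G2/M genes under the deposited scaling, and those of the Notch, cholesterol and fatty acid synthesis, BMP and TGF beta and mature neuron lists changed sign under another scaling.

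Proliferation genes were higher in activated cells. Of 44 tested genes of mitosis and G2/M, 42 rose and 0 fell, over all genes and adjusted over the list alone, with a median difference of 4.46, or 4.20 with genes at background held at their bound (camera adjusted p = 4.03e-23, adjusted p = 0.0543 with an estimated correlation). Top2a, a topoisomerase of replicating and mitotic cells, was at least 51.6-fold higher and the spindle checkpoint kinase Bub1b at least 24.3-fold. Of 42 genes of DNA replication and S phase, 37 rose and 0 fell, or 39 and 1 adjusted over the list alone, with a median of 3.03 (adjusted p = 6.75e-19, adjusted p = 0.0543 with an estimated correlation). The polymerase subunit Pole was at least 31.3-fold higher and the licensing factor Cdt1 at least 26.7-fold. For Cdt1, quiescent array 2 read 9.79 against an activated mean of 12.6. DNA repair genes rose in 24 of 27 cases and fell in 0, also adjusted over the list alone (median 2.40, adjusted p = 1.20e-10, adjusted p = 0.0543 with an estimated correlation), with bounds of 31.7-fold for the checkpoint kinase Chek1, 16.3-fold for Exo1 and 11.9-fold for Rad51ap1. Single members fell when 1 array was left out, 1 of the S phase list without quiescent array 3 or activated array 1, and 1 of the repair list without quiescent array 3.

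Cell cycle brakes moved both ways. Of 21 tested members, 5 rose and 4 fell, also adjusted over the list alone, and the list did not pass (median 0.28, or 0.93 after scaling to the hybridisation controls, adjusted p = 0.51). Cdkn2c, an inhibitor of CDK4 and CDK6, was at least 18.3-fold higher, Btg2 was 3.48 ± 0.57 higher (adjusted p = 0.00117) and the retinoblastoma relative Rbl1 3.45 ± 0.42 higher (adjusted p = 0.000211). Lrig1, a negative regulator of EGF receptor signalling, fell by 2.54 ± 0.37 (adjusted p = 0.000563).

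Chromatin and DNA methylation regulators rose in 22 of 35 cases and fell in 3, also adjusted over the list alone (median 1.36, adjusted p = 2.98e-05, adjusted p = 0.0543 with an estimated correlation). Uhrf1, which recruits the maintenance DNA methyltransferase, was 3.79 ± 0.40 higher (adjusted p = 0.000108) and Hmgb2 3.44 ± 0.24 (adjusted p = 3.16e-05), while the helicase Hells was at least 7.23-fold higher. Hdac11 fell by 2.44 ± 0.61 (adjusted p = 0.0111), a call lost after scaling to the hybridisation controls (adjusted p = 0.0832).

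Genes of protein and RNA production were higher. Cytosolic ribosomal proteins rose in 36 of 41 cases and fell in 0, or 36 and 1 adjusted over the list alone, with a median of 1.65 (camera adjusted p = 8.47e-14, adjusted p = 0.0543 with an estimated correlation). Rps26 was 2.71 ± 0.36 higher (adjusted p = 0.00035) and Rps19 2.52 ± 0.30 (adjusted p = 0.000208). In ribosome biogenesis 14 of 35 genes rose and 0 fell, or 19 and 0 adjusted over the list alone (median 1.10, adjusted p = 7.10e-07, adjusted p = 0.0584 with an estimated correlation). The pseudouridine synthase Dkc1 was 3.90 ± 0.44 higher (adjusted p = 0.000148) and Nop58 2.57 ± 0.34 (adjusted p = 0.00035). Only 8 of these genes rose without activated array 1 and 6 without activated array 2. Translation factors rose in 12 of 22 cases and fell in 0, or 16 and 1 adjusted over the list alone (median 0.89, adjusted p = 8.87e-05, adjusted p = 0.0584 with an estimated correlation), and in 7 without activated array 3, while 1 fell without quiescent array 3. Etf1, a release factor, was 1.97 ± 0.39 higher (adjusted p = 0.00355), and Eif3d 1.82 ± 0.30 (adjusted p = 0.00122), which was not called from the mean of its probe sets (adjusted p = 0.329). After scaling to the hybridisation controls the medians were 1.74 for ribosome biogenesis and 1.53 for translation factors.

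Splicing and protein turnover followed in the same direction. Of 32 genes of the spliceosome and mRNA processing, 21 rose and 0 fell, also adjusted over the list alone (median 1.22, adjusted p = 4.50e-07, adjusted p = 0.0543 with an estimated correlation), and 2 fell without quiescent array 3. The export helicase Ddx39a was 2.70 ± 0.32 higher (adjusted p = 0.000206) and Lsm4 2.70 ± 0.38 (adjusted p = 0.000496). Proteasome subunits rose in 16 of 33 cases and fell in 0, also adjusted over the list alone (median 0.72, adjusted p = 3.71e-06, adjusted p = 0.0543 with an estimated correlation), and in 10 without activated array 2. Psmb6 was 1.99 ± 0.34 higher (adjusted p = 0.00147) and Psmc3 1.72 ± 0.31 (adjusted p = 0.00187). Of 54 respiratory chain genes 13 rose and 1 fell, or 11 and 1 adjusted over the list alone (median 0.40, adjusted p = 0.00924, adjusted p = 0.0584 with an estimated correlation). This call was lost after quantile normalization (adjusted p = 0.0905). Without activated array 1 the higher count was 8, and the lower count ranged from 0 to 4, the latter without quiescent array 3. Atp5l was 1.79 ± 0.42 higher (adjusted p = 0.00809), and Sdha fell by 0.92 ± 0.28 (adjusted p = 0.0269). The Sdha call was lost after scaling to the hybridisation controls (adjusted p = 0.483), without cross-hybridising probe sets (adjusted p = 0.321) and without any single array but quiescent array 3 (adjusted p = 0.0595 to 0.0899). That scaling gave medians of 1.87 for the spliceosome, 1.37 for the proteasome and 1.05 for the respiratory chain list.

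The list of quiescent stem cell and astrocyte genes fell as a whole. All 28 tested members were lower in activated cells, over all genes and adjusted over the list alone, with a median of -2.85 (camera adjusted p = 7.58e-19, adjusted p = 0.0543 with an estimated correlation). The connexin Gjb6 fell by 5.65 ± 0.52 (adjusted p = 6.27e-05) and the bicarbonate cotransporter Slc4a4 by 5.56 ± 0.35 (adjusted p = 3.16e-05). Marker genes of other cell types fell too, with medians of -4.89 for mature oligodendrocyte, -2.59 for ependymal, -2.25 for endothelial and -2.79 for pericyte genes.

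Surface and signalling genes were mostly lower in activated cells. Ion channels and transporters fell in 28 of 38 cases and rose in 0, or 31 and 0 adjusted over the list alone (median -1.97, adjusted p = 9.23e-13, adjusted p = 0.0543 with an estimated correlation), and the urea transporter Slc14a1 was at least 41.0-fold lower. Cell adhesion and extracellular matrix genes fell in 27 of 41 cases and rose in 1, or 27 and 2 adjusted over the list alone (median -1.89, adjusted p = 2.51e-10, adjusted p = 0.0543 with an estimated correlation). The proteoglycan Gpc5 fell by 5.50 ± 0.58 (adjusted p = 0.000106) and the hyaluronan link protein Hapln1 by 5.06 ± 0.38 (adjusted p = 3.25e-05), while the cadherin Cdh4 was 1.68 ± 0.42 higher (adjusted p = 0.0109). G protein coupled receptors and their regulators fell in 16 of 28 cases and rose in 1, also adjusted over the list alone (median -1.24, adjusted p = 7.89e-05, adjusted p = 0.0543 with an estimated correlation). Without quiescent array 1 or quiescent array 3 the higher count was 2. The metabotropic glutamate receptor Grm3 fell by 4.12 ± 0.36 (adjusted p = 5.00e-05), the lysophosphatidic acid receptor Lpar1 was at least 25.4-fold lower, and Rgs16 was 3.54 ± 0.40 higher (adjusted p = 0.000153). The markers of oligodendrocyte, ependymal, endothelial and pericyte identity moved in the same direction as these 3 lists. After scaling to the hybridisation controls the medians were -1.24 for adhesion and -0.59 for receptor genes.

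The lysosome, fatty acid oxidation, glycolysis and lipid synthesis lists were shifted lower in activated cells. Marker lists of other cell types moved the same way on these arrays, with medians of -4.89 (mature oligodendrocyte), -2.79 (pericyte), -2.59 (ependymal) and -2.25 (endothelial). Lysosome genes fell in 20 of 34 cases and rose in 0, or 22 and 0 adjusted over the list alone (median -1.42, adjusted p = 6.23e-08, adjusted p = 0.0555 with an estimated correlation), including the cathepsins Ctsl (fell by 3.76 ± 0.47, adjusted p = 0.000253) and Ctso (fell by 3.51 ± 0.43, adjusted p = 0.000217). Fatty acid oxidation genes fell in 11 of 27 cases and rose in 1, or 12 and 1 adjusted over the list alone (median -0.83, adjusted p = 0.00071, adjusted p = 0.0543 with an estimated correlation). The nuclear receptor Ppara, a regulator of this pathway, was at least 21.9-fold lower and Acsl3 fell by 2.32 ± 0.29 (adjusted p = 0.000253). Ppara read 9.72, 9.30 and 12.7 on quiescent arrays 1, 2 and 3. The 1 higher member, Acads, was not called when any activated array was left out (adjusted p = 0.0572, 0.104 and 0.0757). Glycolysis genes fell in 11 of 17 cases and rose in 0, also adjusted over the list alone (median -1.17, adjusted p = 0.000114, adjusted p = 0.0822 with an estimated correlation), with Pfkp lower by a difference of -3.40 ± 0.39 (adjusted p = 0.000161) and Aldoc, also an astrocyte marker, by -2.87 ± 0.27 (adjusted p = 6.27e-05). Cholesterol and fatty acid synthesis genes fell in 10 of 28 cases and rose in 1, also adjusted over the list alone (median -0.38, adjusted p = 0.00924, adjusted p = 0.0584 with an estimated correlation). The desaturase Scd1 fell by 4.14 ± 0.33 (adjusted p = 3.71e-05). After scaling to the hybridisation controls this list had a median of 0.26 and was no longer called (adjusted p = 0.0516), and the medians of the lysosome, fatty acid oxidation and glycolysis lists were -0.78, -0.18 and -0.53. Its higher count was 2 without quiescent array 3 and 0 without activated array 2 or activated array 3.

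Transit amplifying and neurogenic fate genes rose in 19 of 23 cases and fell in 0, also adjusted over the list alone (median 3.12, adjusted p = 4.18e-11, adjusted p = 0.0625 with an estimated correlation). Egfr is a member of this list and of the sort. Insm1, a transcription factor of neurogenic progenitors, was 5.38 ± 0.60 higher (adjusted p = 0.000148), Cdk6 4.96 ± 0.41 (adjusted p = 3.91e-05) and Rrm2 4.44 ± 0.75 (adjusted p = 0.00131). Neuroblast and newborn neuron genes rose in 9 of 21 cases and fell in 2, or 12 and 2 adjusted over the list alone, with a median of 2.16, or 1.38 with genes at background held at their bound (adjusted p = 0.000474, adjusted p = 0.063 with an estimated correlation). Dpysl3 was 4.35 ± 0.41 higher (adjusted p = 6.27e-05) and the homeobox gene Dlx6 at least 6.30-fold, whereas Stmn4 fell by 3.51 ± 0.61 (adjusted p = 0.00163). Only 1 neuroblast gene fell without quiescent array 2 or without any 1 of the activated arrays.

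Signalling pathways of the niche changed in part. Of 28 Notch pathway genes, 5 rose and 10 fell, or 6 and 10 adjusted over the list alone, and the list did not pass (median -0.20, adjusted p = 0.51). Its median was 0.08 after quantile normalization and 0.44 after scaling to the hybridisation controls. The ligand Dll1 was 4.07 ± 0.41 higher (adjusted p = 8.80e-05), and the effector Hey1 fell by 3.06 ± 0.52 (adjusted p = 0.00133). BMP and TGF beta pathway genes fell in 6 of 19 cases and rose in 0, also adjusted over the list alone (median -0.52, adjusted p = 0.0236, adjusted p = 0.0822 with an estimated correlation). Bmp6 and Tgfb2 were at least 38.4-fold and 50.7-fold lower and Id2, a target of BMP signalling, fell by 3.71 ± 0.33 (adjusted p = 5.35e-05). The BMP call was lost with the mean of all probe sets of a gene (adjusted p = 0.068), its median was 0.13 after scaling to the hybridisation controls, and 1 member rose without quiescent array 3. Markers of other cell types fell with this list, the endothelial genes averaging 9.22 to 10.1 on quiescent and 7.26 to 7.44 on activated arrays, and the oligodendrocyte, pericyte and ependymal list medians being -4.89, -2.79 and -2.59.

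Tested genes that mark other cell types were mostly lower in activated cells. The dim filter left 13 of 15 matched mature oligodendrocyte, 11 of 18 endothelial, 7 of 15 pericyte and 11 of 30 ependymal genes. All 13 tested mature oligodendrocyte genes fell, also adjusted over the list alone, with a median of -4.89, or -4.66 with genes at background held at their bound (adjusted p = 5.27e-08, adjusted p = 0.13 with an estimated correlation). Aspa, Mag and Ermn were at least 27.3-fold, 25.2-fold and 33.2-fold lower. Endothelial genes fell in 8 of 11 cases and rose in 0, or 9 and 0 adjusted over the list alone (adjusted p = 2.54e-05, adjusted p = 0.0543 with an estimated correlation), with bounds of 15.7-fold for the tight junction gene Cldn5 and 11.4-fold for the angiopoietin receptor Tek. Pericyte and smooth muscle genes fell in 5 of 7 cases and rose in 0, or 6 and 0 adjusted over the list alone (adjusted p = 0.00162, adjusted p = 0.0555 with an estimated correlation), and Pdgfrb fell by 4.10 ± 0.59 (adjusted p = 0.000555). Ependymal and motile cilia genes fell in 10 of 11 cases and rose in 1, also adjusted over the list alone (adjusted p = 0.000132, adjusted p = 0.0543 with an estimated correlation). The axonemal gene Dnaic1 was at least 17-fold lower, while Dnah11 was 4.10 ± 0.42 higher (adjusted p = 0.000102).

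**Figure D4:**
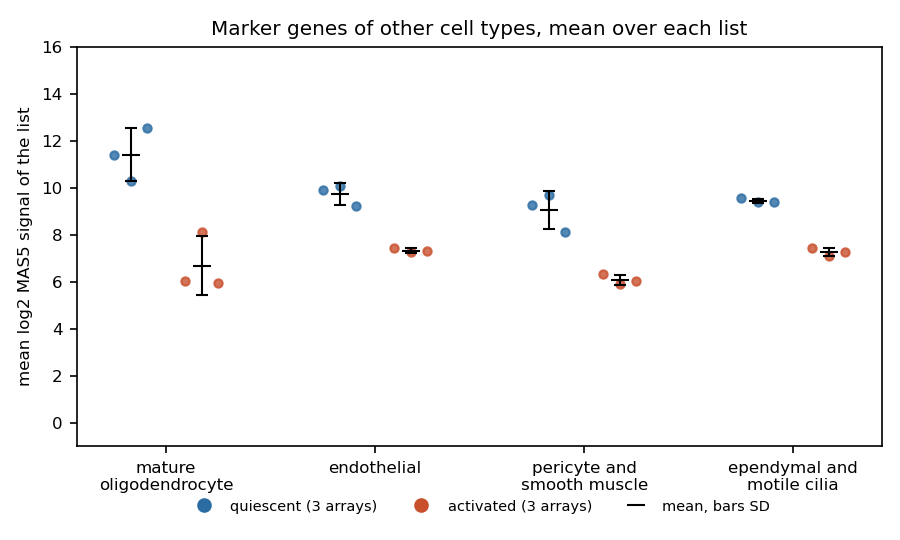
Mean log2 MAS5 signal (vertical axis) over the tested genes of 4 marker lists on each array, with points for arrays, dashes for group means and bars for SD. Mature oligodendrocyte genes averaged 10.3 to 12.5 on quiescent arrays and 5.94 to 8.14 on activated arrays, and the other 3 lists were also higher on every quiescent array.

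Oligodendrocyte precursor and mature neuron genes did not pass as lists. Among 8 tested precursor genes 1 rose and 2 fell, or 1 and 4 adjusted over the list alone (median -1.40, adjusted p = 0.15), and 4 fell without activated array 1. The list was called after scaling to the hybridisation controls (median -0.75, adjusted p = 0.0436) and with 64 added to each signal (adjusted p = 0.038). Bcas1 was at least 58.4-fold lower and Olig2, which is also expressed by transit amplifying cells, was 3.22 ± 0.67 higher (adjusted p = 0.00431). Of 8 mature neuron genes 2 rose and 3 fell, or 3 and 3 adjusted over the list alone (median -0.46, adjusted p = 0.433), with a median of 0.09 after quantile normalization and 0.19 after scaling to the hybridisation controls. The long noncoding RNA Meg3 fell by 4.14 ± 0.46 (adjusted p = 0.000139), and Rbfox3 was at least 7.59-fold higher. Only 1 neuronal gene rose without quiescent array 1 or 2 or activated array 1 or 3.

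Dissociation and immediate early genes were shifted higher in activated cells, with 11 of 26 higher and 3 lower, also adjusted over the list alone (median 0.81, adjusted p = 0.0188, adjusted p = 0.14 with an estimated correlation). Fos was 4.58 ± 0.57 higher (adjusted p = 0.000236) and Egr1 3.87 ± 0.29 (adjusted p = 3.25e-05), while the matricellular gene Ccn1 fell by 3.29 ± 0.67 (adjusted p = 0.00394). The higher count was 6 without activated array 1 and 5 without activated array 2, when 2 fell, and the list was not called with the dim filter at the 60th percentile (adjusted p = 0.0529). Interferon response and antigen presentation genes fell in 6 of 20 cases and rose in 1, or 7 and 1 adjusted over the list alone (median -1.03, adjusted p = 0.00458, adjusted p = 0.0584 with an estimated correlation). Ifit3 was at least 11.1-fold lower and H2-K1 fell by 2.26 ± 0.36 (adjusted p = 0.00105), while Ifit2 was 1.76 ± 0.34 higher (adjusted p = 0.00314). The endothelial, pericyte, ependymal and oligodendrocyte lists, with medians of -2.25, -2.79, -2.59 and -4.89, moved in the same direction as the interferon list. Interferon genes had a median of -0.60 after quantile normalization and -0.38 after scaling to the hybridisation controls, and immediate early genes 1.46 after the latter.

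Lists with fewer than 5 tested members were not tested. Only 4 of 19 matched microglia and macrophage genes were bright enough, and 1 of them, Laptm5, changed, being at least 13.4-fold lower (adjusted p = 0.00219). Of the 19, 12 were above background on at least 1 quiescent array, and the median difference over all 19 was -0.96. Without the dim filter the median over all genes was -0.39. Control probe sets for bacterial transcripts not expected in the sample differed by -1.19. The microglia median therefore cannot be told apart from the shift of dim probe sets. Among 4 sex-linked genes, Xist averaged 13.6 ± 0.30 (SD) on quiescent and 13.1 ± 0.21 on activated arrays, and the Y-linked Eif2s3y 10.8 ± 0.07 and 9.61 ± 0.65, so that transcripts of both kinds were measured in both groups. The Eif2s3y difference of -1.20 ± 0.36 (adjusted p = 0.0255) was not called after scaling to the hybridisation controls (adjusted p = 0.377) or without quiescent array 1, quiescent array 2 or activated array 3 (adjusted p = 0.0584, 0.0712 and 0.0979). The 1 tested blood gene, Alas2, differed by -0.95 ± 0.60 (adjusted p = 0.235).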

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

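Signals outside the gene comparisons were listed here because they differed between the groups in data that the comparisons do not use, and none of these has been explained. Of 3818 bright probe sets with no gene name in the annotation used here, 215 were higher and 795 lower in activated cells by the same limma test. Of all 27022 probe sets tested singly, 3889 were higher and 4501 lower. The median of all probe sets differed by -0.57 between the groups, and the controls for bacterial transcripts not expected in the sample by -1.19. How far this general shift accounts for the unnamed probe sets was not tested. The control probe set for the B2 repeat averaged 15.3 ± 0.64 (SD, n = 3) on quiescent and 14.3 ± 0.02 on activated arrays, a log2 difference of -0.996. The control for the B1 repeat averaged 14.2 ± 0.68 and 13.4 ± 0.06, a difference of -0.82. Between the same groups the hybridisation controls, which do not come from the cells, differed by -0.64 and the 18S ribosomal RNA control by -0.96. The exact permutation p was 0.1 for each repeat, the smallest that 3 arrays against 3 can give. Groups of 3 arrays are too small for the test of single outlying arrays.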

How the results depend on the processing

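Scaling to the hybridisation controls and raising values to background were chosen after seeing the data, and the other alternatives before. Testing each probe set on its own gave 3889 higher and 4501 lower, and 3657 and 4368 at 2-fold, because more features were tested. Scaling to the hybridisation controls gave 3059 higher and 943 lower, and 3031 and 934 at 2-fold, since it shifts the median of all genes to 0.66. Leaving out each array gave 1315 to 2440 higher and 1540 to 2176 lower genes, 1307 to 2223 and 1539 to 2010 at 2-fold, and 13 to 13 lists higher and 14 to 14 lower. The lowest counts came without activated array 2 and the highest without quiescent array 3. Camera with an estimated correlation called 0 lists higher and 0 lower, against 13 and 14, with 23 at an unadjusted p under 0.05. The other counts stayed within 1.5 times. Among 2416 comparisons of 124 named genes with their values under an alternative, 2358 kept direction and call, 58 lost the call and 0 reversed. Genes that lost it under probe set or scaling choices included Eif4ebp1 (adjusted p = 0.229 from the mean of its probe sets), Atp5g1 (0.584), Psmb1 (0.193), Rgs9 (0.109) and, without cross-hybridising probe sets, Rarres2 (0.621). Neu1, Rgs5, Heyl and Ndufb2 each lost it when 1 array was left out, for at least 3 of the arrays. The cause was not tested. With the replicate number as a block, 1955 genes were higher and 1979 lower, 1858 and 1927 at 2-fold, and 3764 calls kept their direction. Deviations of same-numbered arrays had correlations of 0.06, -0.02 and 0.03, against -0.08 to 0.05 for the other pairs. With 3 arrays per group these values cannot show whether same-numbered arrays share an origin. Signal over background limits dim genes: 320 higher calls had a quiescent array at background and 270 lower calls an activated one.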

Other observations

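The tests of explanations below, and the immediate early pattern itself, were chosen after the results were seen. Explanations were tested for 4 patterns and 3 are weighed. The fourth, dim probe sets reading higher on quiescent arrays, was set aside in favour of the immediate early genes after both had been examined. Its values were a difference of -1.19 in the unspiked controls and of -0.55 (SE 0.13, over arrays) in the unspiked less the hybridisation controls, activated minus quiescent.

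Different probe sets of a gene sometimes moved in opposite directions. Of 1532 genes with at least 2 called probe sets, 37 (2.42%) had calls in both directions, 32 of them at 2-fold or more in each. Mfsd11 had probe sets at 2.89 ± 0.76 and -2.82 ± 0.58, and Prxl2a at 3.34 ± 0.70 and -2.50 ± 0.26. Atp5g1, a subunit of ATP synthase, had 2.58 ± 0.38 and -2.04 ± 0.67, and the eye and forebrain homeobox gene Six3 had 1.88 ± 0.53 and -1.997 ± 0.69. Whether these probe sets detect different transcripts was not tested.

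Mature oligodendrocyte genes showed the lowest list median in activated cells, and their level varied together among arrays of one group. The mean pairwise correlation of the 13 members' deviations from their group means was 0.63, above all 10000 random lists matched on expression (95th percentile 0.12), which is what oligodendrocytes or their RNA in the sorted cells may produce, in amounts that vary between arrays. The quiescent stem cell and astrocyte list also lay high, at the 99.9th percentile (0.25), so shared regulation remains open, while neuroblast, endothelial, pericyte and ependymal genes lay at percentiles 90.2, 77.5, 43.4 and 16.6. The members Cnp, Mbp and Mal averaged 13.3, 13.0 and 12.9 on quiescent and 11.1, 7.66 and 8.003 on activated arrays, none of the list is in another fixed list (0 of 13), and 9 of 13 were above background on all activated arrays, in a sort that required the GFAP reporter and CD133. Array scaling or background is argued against. With values raised to background and the shift of the hybridisation controls removed, the median was still -4.01 (SE 0.26, over genes and not arrays). Without these corrections the list averaged 10.3 to 12.5 on quiescent and 5.94 to 8.14 on activated arrays. A difference between the sorted populations themselves was not tested.

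Cd24a transcript was higher in activated cells of a sort that removed CD24 protein. A single misbehaving probe set is argued against, since the smallest difference among its 3 probe sets was 3.45 ± 0.35. Neuroblasts carried into the sort could raise it, and 40% of the other 20 tested neuroblast genes rose (8 higher, 2 lower), which leaves this open because the levels of these genes in neuroblasts are not in the tables. A difference between the stem cell populations themselves was not tested.

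Dissociation and immediate early genes were higher in activated cells as a list. Its 4 tested heat shock genes had a median of -0.23 (SE 0.82), with Hsph1 higher and Hspa1b lower, and the other 22 had 0.94 (SE 0.43), with 10 higher and 2 lower, and the difference between these parts was not tested. Stress of dissociation and sorting, which could raise both parts, remains open because 4 genes that go both ways decide nothing. The list was still called after quantile normalization and median centring. Centring shifts all genes of an array alike, which camera's comparison with other genes hardly registers. The 22 then had medians of 1.18 (SE 0.43) and 0.85 (SE 0.43). The whole list had 0.99 and 0.73, and 1.46 after scaling to the hybridisation controls. Array scaling remains open because 0.85 lies within 2 standard errors of 0, an SE over genes that does not measure spread between arrays. Camera with an estimated correlation lost the call (adjusted p = 0.14), which does not bear on scaling. A difference between the sorted populations themselves was not tested.

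Only 10 ways of dividing the 6 arrays into 3 and 3 exist, too few for a share under 0.05. The real division gave 4044 changed genes, 3803 at 2-fold and 27 lists, and 1 of the 10 divisions, the real one, reached each count. The highest of the others gave 0 genes, 0 genes and 22 lists. Camera at a preset correlation thus called many lists in a division that mixes the groups. Every other division mixes the groups unequally, so part of the real difference remains between its sides and also widens the spread within them. These counts therefore do not show what arrays without a group difference would give.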
